A study of Mus musculus with 3 samples.

How the data were processed

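Single-cell RNA sequencing was done on cells of mouse inguinal white adipose tissue, the fat pad under the skin of the groin. There were 3 libraries, each 1 sample of its own genotype: Tert wild type, Pdgfra-Cre; Tert fl/fl and Pdgfrb-Cre; Tert fl/fl. Tert encodes the catalytic subunit of telomerase, and the Cre drivers delete the floxed gene in cells that use the promoter of either platelet-derived growth factor receptor, both found in mesenchymal cells. Per the labels, dead cells and red blood cells were removed before loading, and libraries were made with the 10x 3' v3 chemistry and sequenced on an Illumina NextSeq. The title of the wild-type sample also carries the abbreviation PBS, which the labels do not explain.

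The authors deposited counts: unique molecular identifier (UMI) counts per gene and barcode, not normalised, made by the authors with Cell Ranger 3.1.0 and STAR 2.6 on the mouse build mm10. The files list 31053 features, the same in every library, and barcodes with at least 500 UMIs (the lowest held 500, 500 and 502). Coordinates were taken from GENCODE M21 on GRCm38, in which 99.62% of the gene identifiers were found. Symbols shared by several identifiers (71 features) were kept apart by identifier. Ccl21a, Terc, Ccn1, Ccn2, Ccl19, Aldoa and Sepp1 of the gene lists could not be measured by symbol in these files.

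A barcode was kept with at least 500 genes and at most 15% mitochondrial UMIs. Scrublet, run through scanpy 1.11.5 in each library, ranked doublet scores, and the highest 0.8% for each 1000 kept barcodes were left out. Counts per cell were scaled to 10000 and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours led to 28 Leiden clusters at resolution 1 with no batch integration, since library and genotype are the same thing here. Mitochondrial, ribosomal protein and Y-linked genes and Xist were not used for clustering. Clusters were named from marker lists of 19 cell classes, by the class with the highest mean log2 CPM of its markers relative to the mean over clusters, among classes with at least 3 markers each seen in at least 10% of the cluster's cells. A cluster stayed unnamed if its 10 leading genes held more markers of another class. It also stayed unnamed if they held no marker of its own class, unless its share of own markers seen in 25% of cells led every other class by 25 points and it was not shallow. The part of this rule that leaves clusters unnamed was settled after the clusters were seen. Every class name therefore means "like that class by RNA markers": the stromal progenitor-like cells are called stromal cells, the macrophage- or monocyte-like cells macrophages, and so on.

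Shares of kept cells carry exact Clopper-Pearson intervals. UMIs of a class were summed per library and scaled to the UMI total of that class as CPM with exact Poisson intervals, and a fold is a ratio of CPM with an exact conditional binomial interval. All intervals are at the 95% level and cover counting error alone, not differences between animals. Those of CPM and folds treat each UMI as a separate draw, so they leave out spread between the cells of a library and can be too narrow. With 1 library per genotype no test between groups was made, and no gene was called changed. A count of 0 was set to a limit of 3 counts, except in cycling shares, which give the upper end of the interval. The log2 ratio has 10 CPM added on both sides. Classes with at least 100 cells in both libraries were compared, which held for 6 classes, 3 of them in every pair.

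Before the data were examined, 24 gene lists were fixed: telomerase and telomere maintenance, p53 targets, senescence-associated genes, interstitial Dpp4-type progenitors, committed Icam1-type preadipocytes, F3-type regulatory stroma, adipogenesis, extracellular matrix, inflammatory chemokines and cytokines, interferon response, major histocompatibility complex (MHC) class II, immediate early genes, heat shock, hypoxia and glycolysis, nuclear oxidative phosphorylation, mitochondrial genome, proliferation, oxidative stress, beige and thermogenic genes, endothelial subtypes, resident, lipid-associated and inflammatory macrophage or monocyte genes, and T cell states. Of each, the median log2 ratio over members with at least 10 CPM in either library is given, with its percentile among 10000 random lists matched on expression in 20 bins. This percentile describes where the list lies among genes of these libraries and is no test between genotypes. Some lists share members, so their medians are not independent. The senescence and inflammatory lists share Ccl2, Ccl7, Il6, Cxcl1 and Cxcl12, among others. The senescence and p53 lists share Cdkn1a and Gdf15, and the p53 and immediate early lists share Btg2. Immediate early, heat shock, interferon, inflammatory and mitochondrial lists were computed beyond the stromal cells after the data were seen.

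Named genes follow a rule fixed before the data were examined: at least 50 CPM and 20 UMIs in a library of the pair, CPM at least 1/3 of the highest class, the 10 highest and 10 lowest log2 ratios in stromal cells, 5 each way elsewhere, and extreme members of each list, of which some are not reported. Mitochondrial, ribosomal, Y-linked, immunoglobulin, T cell receptor, haemoglobin and predicted genes were left out of it. Tert, Pdgfra and Pdgfrb are named in any case, and the position-linked regulators (Wt1, Tbx15 and others), the haemoglobin and lymphocyte genes that mark free RNA, and Gdf15 and Cxcl2 with few wild-type UMIs are named after their values were seen. A cycling cell had UMIs of at least 2 of 18 cell-cycle genes after thinning to 1500 UMIs, with shallower cells left out. The library distance is the standard deviation of the log2 ratio over genes with at least 50 CPM in any library.

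Alternatives were a stricter cell filter (1000 genes, 5% mitochondrial UMIs), no removal by doublet score, Leiden resolutions of 0.5 and 2, calls per cell without clusters, other scalings (size factors by the median of ratios, or CPM without mitochondrial and ribosomal protein genes), a mean over cells, a pseudocount of 1, other minimum levels for lists, other thinning depths (none, 3000) and shares among cells that are not lymphoid. Leaving out stromal cluster 24 or 18 was added after the data were seen. It was run for list medians and, for cluster 18, the wild-type cycling share. Of single genes, only the position-linked regulators were counted without cluster 24. The rule that a sign change counts as a reversal where the main value stood apart from 0 was set after a first count of every sign change. A gene stood apart when its interval excluded 0, and a list median when its interval over members excluded 0 or its percentile lay outside the central 95% of random lists, so some medians count by percentile alone. A list median counted as moved when it left the order-statistic interval of the median over its members, a gene, share or library distance when it left its 95% interval (for the distance, from 1000 bootstrap draws over genes). The 9 lists given in full for every alternative that moved them were picked after their values were seen, before the alternatives were judged. Intervals, list percentiles and directions were tested on simulated data. These were Poisson draws from pooled stromal levels, without spread between cells or free RNA. They check the calculation, not how well the intervals cover the spread in these libraries. The work used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.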

Results

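Transcriptomes of single cells from mouse inguinal white adipose tissue were compared between Tert wild type, Pdgfra-Cre; Tert fl/fl (Pdgfra-Cre) and Pdgfrb-Cre; Tert fl/fl (Pdgfrb-Cre), to see how deleting telomerase in mesenchymal progenitors alters the cells of the fat pad. Each genotype was 1 library, so genotype and library cannot be separated, and every difference given is a difference between libraries. The libraries held 13352288, 14438471 and 30826733 UMIs in 4124, 2310 and 4355 barcodes, in the order wild type, Pdgfra-Cre and Pdgfrb-Cre, which is kept wherever 3 values are listed. Of these, 2668, 1409 and 3903 cells were kept, with medians of 3321, 7522 and 5675 UMIs per cell. Barcodes under 500 genes made up 29.1%, 34.9% and 4.8% of the libraries.

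Stromal cells, the progenitor compartment marked by Pdgfra and collagen genes, made up 9.41% of wild-type cells (95% interval 8.33 to 10.6), 43.9% of Pdgfra-Cre cells (41.3 to 46.6) and 14.6% of Pdgfrb-Cre cells (13.5 to 15.7). Blood endothelial cells, which line the vessels, made up 23.4% (21.8 to 25), 8.73% (7.31 to 10.3) and 5.10% (4.43 to 5.84). B cells and T cells were the other large classes: B cells were 23.0%, 1.77% and 24.4%, and T cells 22.0%, 11.1% and 43.0%. Of the 25 Pdgfra-Cre B cells, 12 had at least 3 UMIs of Xist and no Y-linked UMI, while 66.5% of the cells of that library had a Y-linked UMI. Mesothelial cells, which cover the surface of internal organs and of visceral fat, made up 9.23% of Pdgfra-Cre cells (7.77 to 10.9), against 2 of the Pdgfrb-Cre cells and 0 of the 2668 wild-type cells, which allows a share of up to 0.112% at 3 counts (0.138% by its interval). Dendritic cells were 3.49% and 0.589% of wild-type and Pdgfrb-Cre cells and 0 of the 1409 Pdgfra-Cre cells, which allows up to 0.213% at 3 counts (0.262% by its interval), and the clusters named dendritic at the other Leiden resolutions held none either, but under the stricter filter 1 of the clusters named dendritic held 11 Pdgfra-Cre cells.

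Among the smaller classes, mural cells, the contractile cells around vessels, made up 4.69%, 2.34% and 1.08%, macrophages 4.80%, 7.03% and 4.74%, and NK cells 2.40%, 13.3% and 3.25%. Several of these shares depended on how cells were grouped. Across other cell filters and groupings the NK share of Pdgfra-Cre was 2.98 to 5.25% and its T cell share 19.3 to 24.1%, and with doublets kept its B cell share was 0.840%. The same settings gave wild-type mural shares down to 1.91% and up to 7.53%, wild-type macrophage shares down to 1.47%, and, with doublets kept, 0% dendritic cells. The stricter filter gave Pdgfrb-Cre shares of 28.2% for stromal cells and 13.9% for B cells. Lymphoid cells together (B, T, NK and plasma cells) were 47.8%, 26.3% and 71.5%. With lymphoid cells left out, stromal cells were 18.02%, 59.6% and 51.2% of the remainder. Cluster 0, led by cell-cycle genes and not assigned to a class, held 5.21%, 0.568% and 1.49% of cells. Removal of dead and red cells before loading and the unequal depth of the libraries can set these shares, and the intervals cover counting error alone. An inguinal fat pad can also bring its lymph node, in unequal parts between libraries, which was not tested. The lymphoid shares, and the stromal shares they dilute, therefore need not be those of the fat itself.

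**Figure D1:**
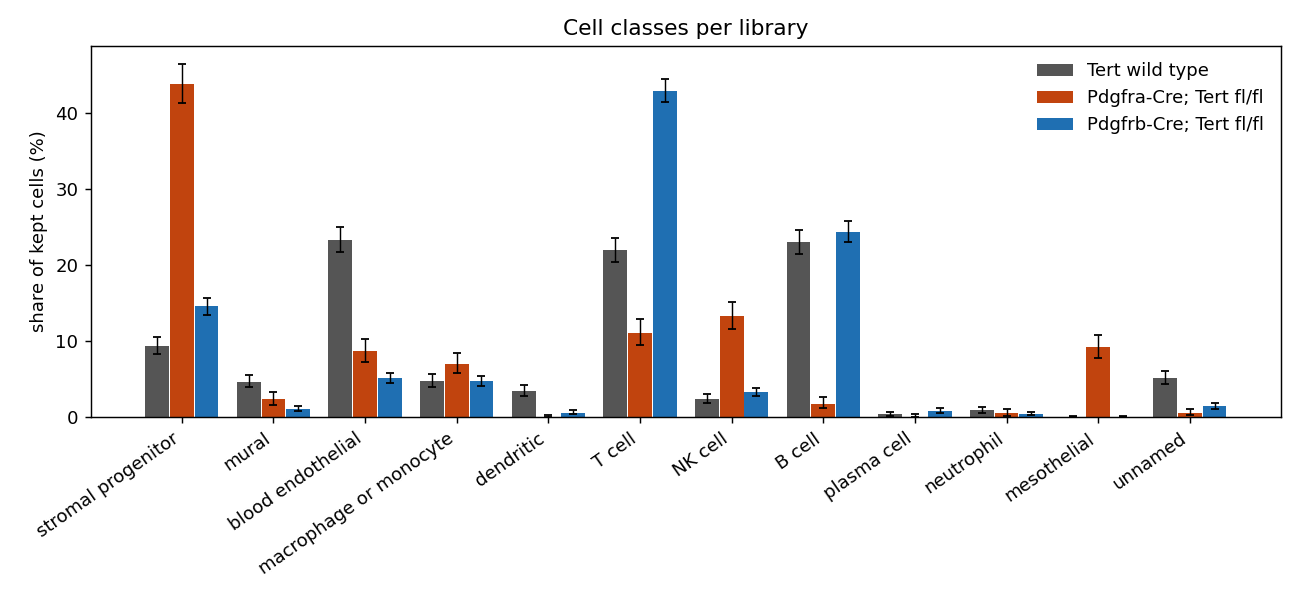
Share of kept cells (%) for each cell class with at least 20 cells in a library, by library; bars start at 0 and black lines are 95% Clopper-Pearson intervals for counting error. Stromal cells reach 43.9% in the Pdgfra-Cre library and mesothelial cells 9.23%.

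The stromal class joined clusters that the libraries shared unequally: cluster 1 held 160, 5 and 13 cells, cluster 14 held 27, 22 and 349, cluster 16 held 34, 97 and 206, cluster 18 held 30, 0 and 0, and cluster 24 held 0, 495 and 1. In all, 251, 619 and 569 stromal cells were compared, with medians of 1667, 9687 and 10500 UMIs per cell. Tert itself (ENSMUSG00000021611, chromosome 13, 73626911 to 73649843 of GRCm38) gave 3, 4 and 1 UMIs in stromal cells and 14, 7 and 10 in all kept cells. That is 3.42 (0.706 to 10.0), 0.702 (0.191 to 1.80) and 0.165 CPM (0.00418 to 0.919) in stromal cells. The deleted exons are not given in the sources used here and a 3' tag can lie outside them, so these counts do not check the deletion. Transcripts of the driver gene Pdgfra stood at 411 (370 to 456), 521 (502 to 540) and 199 CPM (188 to 210) in stromal cells, and those of Pdgfrb at 119 (97.0 to 144), 147 (137 to 157) and 101 CPM (93.1 to 109). Pdgfra was 2.07-fold lower in Pdgfrb-Cre than in wild type (1.84 to 2.33). The Pdgfrb gap between those libraries (ratio 0.850, 0.690 to 1.06) lay within counting error and changed sign in a mean over cells, at a log2 ratio of 0.23.

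The comparison of Pdgfra-Cre with wild type asks what loss of Tert under the Pdgfra driver does to the progenitors. It cannot answer this alone, since 495 of the 619 Pdgfra-Cre stromal cells formed cluster 24, which held 0 wild-type cells. Regulators of body position differed between these stromal cells as well (given below), so the values that follow cannot be assigned to Tert. Pdgfra-Cre stromal cells had far fewer transcripts of interstitial progenitors and of extracellular matrix, and more of the immediate early and oxidative stress lists given below. Trf, encoding the iron carrier transferrin, was at 1262 against 14.8 CPM (85.0-fold higher, 49.7 to 160), Sult1e1, an oestrogen sulfotransferase, at 1566 against 26.3 (59.7-fold, 39.7 to 94.1), and Hsd11b1, which regenerates active glucocorticoid, at 661 against 43.4 (15.2-fold, 11.1 to 21.6). In the other direction, Cthrc1, a secreted protein of remodelling matrix, was 135-fold lower (80.5 to 244), the interstitial progenitor genes Pi16 and Dpp4 were 13.3-fold (12.3 to 14.5) and 9.05-fold lower (7.30 to 11.2), and Col1a1, the main fibrillar collagen chain, was 9.25-fold lower (8.92 to 9.59). Igfbp5, which binds insulin-like growth factors, was 19.99-fold lower (18.4 to 21.7). Trf lies on chromosome 9 (103204001 to 103230444), Cthrc1 on chromosome 15 (39076932 to 39087121) and Igfbp5 on chromosome 1 (72857932 to 72874884).

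The other genes at the top of the ranking in Pdgfra-Cre stroma had log2 ratios to wild type of 3.75 for the neuropeptide gene Nmb, 3.75 for the collagen VI chain Col6a5, 3.71 for the neutrophil-attracting chemokine Cxcl1, 3.65 for Fndc5, 3.58 for Fosb, 3.35 for Tiparp and 3.34 for the copper carrier Cp. At the bottom were Nov at -4.08, Dmkn at -3.52, the B cell-attracting chemokine Cxcl13 at -3.45 and the Wnt inhibitor Sfrp4 at -3.38. Cxcl5, a chemokine, was at 108 CPM in wild type and 0 UMIs in Pdgfra-Cre, at least 206-fold lower. C1rb, a complement protease gene, was at 174 CPM against 2 UMIs (ratio 0.00202, 0.000243 to 0.00743), and Ifi202b was at 154 CPM against 1 UMI. Reads of both can be shared with close paralogs (C1ra and other Ifi200 family genes), which makes their levels uncertain.

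By gene list, 16 of 16 measured interstitial Dpp4-type genes were lower in Pdgfra-Cre stroma (median log2 ratio -2.54, percentile 0 among random lists), among them Sema3c at -3.34 and Efhd1 at -3.07. The extracellular matrix list had 25 of 28 members lower (-1.20, percentile 0), with Col3a1 and Postn at -2.78 each, Col14a1 at -2.75 and Fn1 at -2.56. Committed Icam1-type preadipocyte genes had 11 of 16 members higher (1.08, interval -0.84 to 1.80, percentile 99.99), such as Sparcl1 at 2.89 and Col15a1 at 2.21, while Cxcl14 was at -1.96. F3-type regulatory stroma had 6 of 9 higher (0.57, percentile 95.7), with F3 at 1.94 but Meox2 at -1.83, and adipogenesis had 14 of 19 higher (0.58, interval -0.25 to 1.55, percentile 99.8), led by Klf9 at 2.55 and Cebpd at 2.03. Fabp4, the fatty acid carrier of the fat cell lineage, was 3.02-fold higher (2.61 to 3.50), and Pparg, the master regulator of fat cell formation, was 5.27-fold higher (2.01 to 19.6) on 4 wild-type UMIs.

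Of the stress-linked lists, the immediate early and oxidative stress lists ran higher. The inflammatory and heat shock medians were above 0, but their intervals over members held 0. Immediate early genes, which respond within minutes to stimulation or tissue handling, were higher in 25 of 25 cases (1.89, percentile 100). Among them were Egr1, 9.44-fold higher (8.57 to 10.4), Nfkbiz, 11.2-fold higher (8.21 to 15.7), Atf3 at a log2 ratio of 3.11 and Socs3 at 3.09. Inflammatory chemokines and cytokines were higher in 12 of 21 and lower in 9 (median 0.79, interval -1.84 to 1.64, percentile 100). Oxidative stress genes were higher in 17 of 20 (0.55, percentile 99.5), with the metallothionein Mt1 8.14-fold higher (7.45 to 8.91). Heat shock genes stood at 0.51 (10 of 14 higher, percentile 95.9), from Hspa5 at 1.70 to Hspa1a at -2.22, whose reads can be shared with Hspa1b. Interferon response genes were lower in 17 of 24 (-0.68, interval -0.99 to 0.11, percentile 0), with Ifi27l2a at -2.72. Of these 24, 19 were higher in another class than in stromal cells. The mitochondrial genome was lower in 13 of 13 (-1.0, percentile 0), with mt-Co3 at -1.56. Proliferation genes were lower in 24 of 25 (-1.51, percentile 0), with Top2a and Ube2c at -2.74 each, and 23 of these 25 were higher in another class.

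MHC class II genes, normally of antigen-presenting cells, were lower in 5 of 5 (-2.85, percentile 0), with Cd74 at -4.21. All 5 were higher in another class. Free RNA differed in the same direction and can add to the gaps of these 3 lists, since the B cell gene Cd79a stood at 35.4, 2.46 and 6.76 CPM in stromal cells and the T cell gene Cd3e at 23.97, 0.351 and 4.62. The haemoglobin gene Hbb-bs went the other way, at 7.99, 1424 and 0.825 CPM.

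Of the lists tied to telomere loss, telomerase and telomere maintenance genes were higher in 6 of 11 (0.05, percentile 64.8), with Naf1 at 0.98 and Ten1 at -0.32, and the sign of this median turned under both other scalings (-0.02 and -0.06). Stn1 stood at 0.96 on 2 wild-type UMIs. Targets of p53 were higher in 11 of 17 (0.26, percentile 93.8, or 0.97 over members of at least 50 CPM), among them Cdkn1a, the cell-cycle inhibitor p21, 4.67-fold higher (3.65 to 6.07), Btg2 at 2.003 and Plk2 at 1.47. Gdf15 rested on 1 wild-type UMI and had a ratio of 30.8 (5.46 to 1220). Senescence-associated genes were higher in 12 of 24 (0.28, percentile 93.0), with Ccl7 at 2.37 and Mmp3 at -3.31. Hypoxia and glycolysis stood at 0.18 (13 of 19 higher, percentile 75.8, Adm at 2.29 and Hk2 at 1.85). The nuclear oxidative phosphorylation list (0.06, 20 of 32 higher, percentile 44.9, Sdhc at 0.54) and the 3 measured beige genes (0.05, 2 higher, percentile 52.2) turned to -0.03 and -0.05 with size factors, and to -0.08 and -0.10 with CPM taken without mitochondrial and ribosomal protein genes.

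Cluster 24 decided part of these values, since it supplied 495 of the 619 Pdgfra-Cre stromal cells. In an alternative chosen after the data were seen, the other 124 cells gave medians of -0.17 for Dpp4-type genes, 0.01 for Icam1-type genes, -0.0001 for adipogenesis, -0.61 for extracellular matrix, -0.32 for inflammatory genes, -0.26 for senescence-associated genes, 0.52 for p53 targets and 1.16 for immediate early genes, against wild type. Among the ranked genes, Sult1e1 was a leading gene of cluster 24, and Cthrc1 and Nov of cluster 18 (30, 0 and 0 cells). Ratios of ranked genes were not recomputed without either cluster, so these cells can carry part of them.

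**Figure D2:**
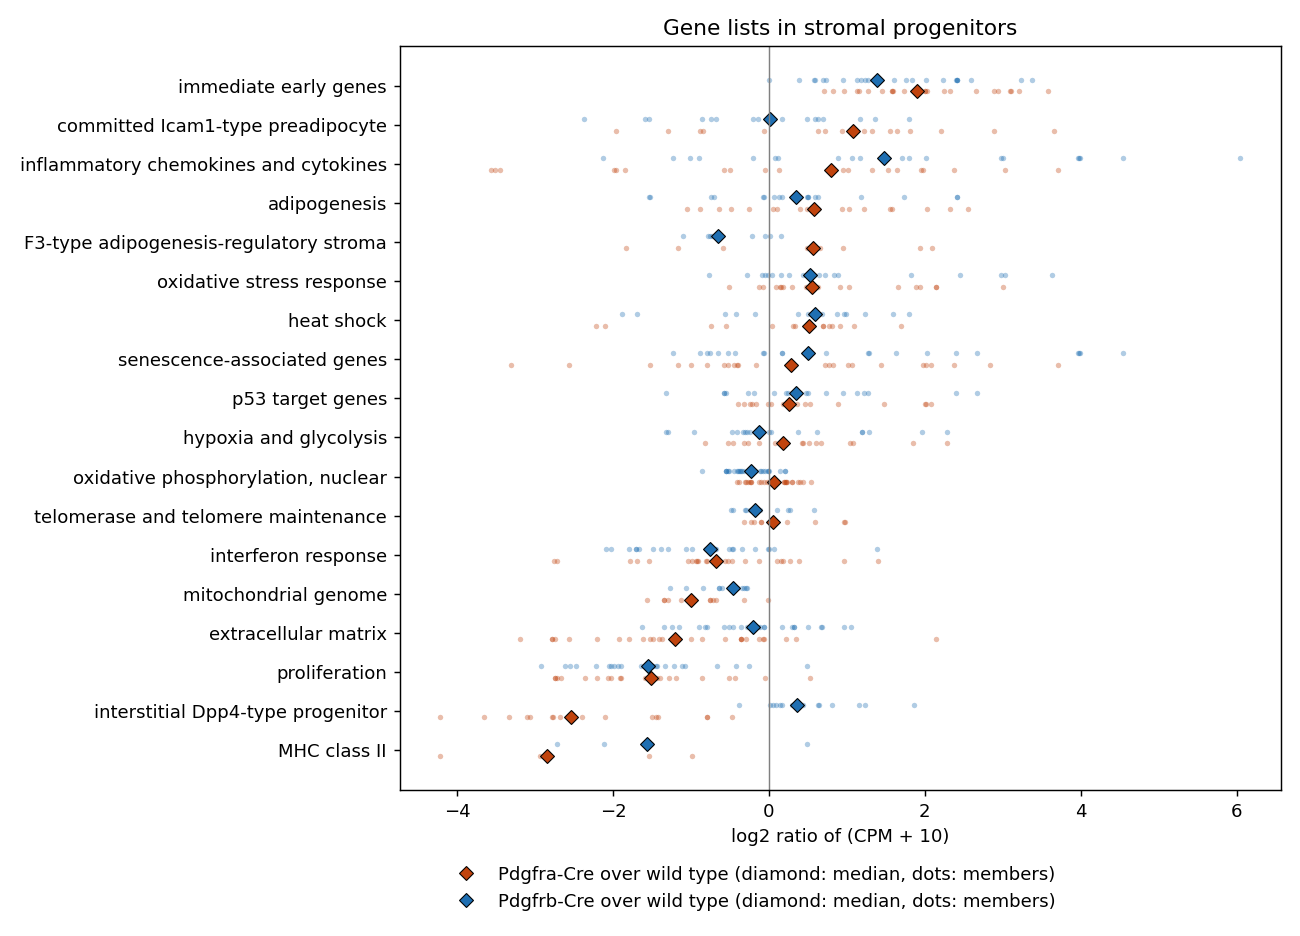
Log2 ratio of CPM plus 10 to wild type for each gene list in stromal cells, in Pdgfra-Cre (orange) and Pdgfrb-Cre (blue); diamonds are list medians, dots are single members, and no replicate error can be drawn with 1 library per genotype. Interstitial Dpp4-type genes lie at -2.54 in Pdgfra-Cre and 0.36 in Pdgfrb-Cre, while immediate early genes lie at 1.89 and 1.39, and telomere maintenance genes (0.05 and -0.18) lie near 0, the first with a sign that turned under the other scalings.

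The comparison of Pdgfrb-Cre with wild type asks the same of the Pdgfrb driver. Pdgfrb-Cre stromal cells carried more transcripts of the inflammatory, immediate early and oxidative stress lists, and fewer of the proliferation and interferon response lists. Has1, which makes the matrix sugar hyaluronan (chromosome 17, 17843323 to 17855205), was at 1869 against 27.4 CPM (68.2-fold higher, 45.8 to 107). Cxcl1 (chromosome 5, 90891241 to 90893115) was at 3215 against 128 CPM (25.2-fold, 20.9 to 30.6), Il6, an inflammatory cytokine, at 402 against 16.0 (25.1-fold, 14.95 to 46.1) and Tnfaip6, a hyaluronan-binding protein, at 2035 against 114 (17.8-fold, 14.7 to 21.9). The 14 wild-type UMIs of Il6 came from 1.59% of the 251 stromal cells. Has1 and Tnfaip6 were leading genes of cluster 14 (27, 22 and 349 cells), whose unequal share can add to their folds. No alternative left that cluster out. Cxcl2, a chemokine, had 0 UMIs in wild type and was at least 190-fold higher. Cthrc1 was 14.6-fold lower (12.0 to 17.9), the interferon regulator Irf7 5.05-fold lower (4.15 to 6.14), the mitotic kinase gene Cdk1 36.2-fold lower (17.5 to 83.9) and Col1a1 3.101-fold lower (3.02 to 3.19).

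The next genes by log2 ratio in Pdgfrb-Cre stroma were Tiparp at 3.99, the metallothionein Mt2 at 3.63, Ifrd1 at 3.60, Myoc at 3.45, Fosb at 3.38 and the cytokine gene Tnfsf9 at 3.22. Toward the bottom were the complement genes C1rb (263-fold lower, 101 to 978) and C1s2 (40.1-fold lower, 23.1 to 74.8), whose reads can be shared with C1ra and C1s1, and Ifi202b with 0 UMIs (at least 312-fold lower). Pdgfrl was at a log2 ratio of -3.08, Spata7 at -2.38, Cxcl5 at -2.12 and Thap1 at -2.06.

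Inflammatory chemokines and cytokines were higher in 17 of 22 members in Pdgfrb-Cre stroma (median 1.48, percentile 100), and immediate early genes in 24 of 25 (1.39, percentile 100), among them Klf4 at 2.41 and Zfp36 at 2.40. Senescence-associated genes were higher in 14 of 23 (0.50, interval -0.43 to 2.02, percentile 99.8). They included the monocyte-attracting chemokines Ccl7 at 3.98 and Ccl2 at 3.97, both also in the inflammatory list. Targets of p53 were higher in 13 of 19 (0.35, interval -0.27 to 1.13, percentile 99.8, with 0.23 to 1.13 across the alternatives). Among them, Cdkn1a, also in the senescence list, was 5.86-fold higher (4.58 to 7.62), Plk2 was at 1.26 and Ddit4 at -1.31. Gdf15 had a ratio of 53.5 (9.54 to 2117) on 1 wild-type UMI. Oxidative stress genes were higher in 15 of 20 (0.52, percentile 99.8), with Hmox1, a heme-degrading enzyme, at 2.97 and Txnrd1 at 2.45. Heat shock genes were higher in 9 of 14 (0.59, interval -0.57 to 1.23, percentile 98.8), with Hspa5 at 1.80 and Hspa1a at -1.89. The senescence, p53 and heat shock intervals over members held 0.

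Dpp4-type progenitor genes were higher in 15 of 16 (0.36, percentile 95.7), such as Limch1 at 1.86 and Cd55 at 1.23. Adipogenesis genes were higher in 13 of 19 (0.35, interval -0.08 to 0.63, percentile 98.9), with Cebpb at 2.41 and Klf9 at 1.74. Proliferation genes were lower in 24 of 25 (-1.55, percentile 0, Ube2c at -2.92 and Top2a at -2.62), interferon response genes in 22 of 24 (-0.76, percentile 0, Isg15 at -2.02, with 19 of the 24 higher in another class), MHC class II genes in 4 of 5 (-1.56, percentile 0, Cd74 at -2.72) and the mitochondrial genome in 13 of 13 (-0.46, percentile 0.14, mt-Co3 at -0.63). Free RNA of lymphoid cells, also lower here than in wild type, can add to the first 3. Lower values also held for 7 of 9 F3-type genes (-0.66, percentile 0.06, Gdf10 at -1.11), though a mean over cells turned that median to 0.53, and for 28 of 32 nuclear oxidative phosphorylation genes (-0.23, percentile 0.57, Atp5k at -0.86). Extracellular matrix genes were lower in 19 of 28 (-0.20, percentile 3.18), Col3a1 at -1.35 and Postn at -1.24 among them, with a median of 0.0034 in a mean over cells. Telomere maintenance stood at -0.18 (6 of 10 lower, percentile 37.6, Naf1 at 0.58 and Ten1 at -0.46), hypoxia and glycolysis at -0.13 (11 of 19 lower, percentile 20.2, Hk2 at 2.28 and Ndrg1 at 1.97) and Icam1-type genes at 0.01 (8 of 16 higher, percentile 57.4, Icam1 at 1.80 and Apoe at -2.37), a sign that turned under both other scalings (-0.01 and -0.05).

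Cycling stromal cells, with UMIs of at least 2 cell-cycle genes after thinning to 1500 UMIs, were 31 of 144 in wild type (21.5%, 15.1 to 29.1), 0 of 575 in Pdgfra-Cre (up to 0.640%) and 1 of 554 in Pdgfrb-Cre (0.181%, 0.00457 to 1.002). Thinning left out 107, 44 and 15 shallower stromal cells, most of them of wild type. Unthinned shares were 15.1%, 0.969% and 1.41%. Without cluster 18, an alternative chosen after the data were seen, 4 of 116 wild-type stromal cells were cycling (3.45%), and the proliferation median was -0.0495 for Pdgfra-Cre and -0.68 for Pdgfrb-Cre. Blood endothelial cells had a cycling share of 6.35% (4.07 to 9.38), 0 of 93 (up to 3.89%) and 1.11% (0.134 to 3.93).

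Genes that differed from wild type the same way in both Cre libraries were ranked by the smaller log2 ratio. Higher in both were Cxcl1, Fosb, Tiparp, Tnfaip6, Mt1 (3.003 and 3.03), Zfp36 (2.89 and 2.40), Klf4 (2.32 and 2.41), Ifrd1, the cyclin gene Ccnl1 and the early response gene Ier3. Lower in both were Cthrc1, Cdk1, Irf7, Cxcl5, Col1a1, Spata7, Thap1, C1rb, C1s2 and Ifi202b, the last 3 with reads that can be shared with paralogs. Cdk1 had 0 UMIs in Pdgfra-Cre stromal cells, at least 102-fold lower than wild type.

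Between the Cre libraries, which asks whether the drivers give different outcomes, Pdgfrb-Cre stroma held more transcripts of interstitial progenitors and of inflammation, and Pdgfra-Cre stroma more of Icam1-type preadipocytes. Without cluster 24 the Icam1-type median reversed and the Dpp4-type median was smaller (values below). Of the genes named next, Sult1e1, Penk and Inmt were leading genes of cluster 24, and Has1, Pi16 and Fndc1 of cluster 14. In Pdgfrb-Cre, Igfbp5 was 44.8-fold (41.7 to 48.2), Has1 57.0-fold (49.3 to 66.2), the epithelial-type secreted protein Dmkn 111-fold (79.6 to 161), the matrix protease Mmp3 68.8-fold (47.8 to 103) and Pi16 14.2-fold higher. Akr1c18, a progesterone-inactivating enzyme, had 0 UMIs in Pdgfra-Cre and was at least 468-fold higher in Pdgfrb-Cre. Lower there were Col6a5 (256-fold, 158 to 449), Agt, which encodes angiotensinogen (87.7-fold, 61.3 to 130), Trf (24.4-fold), Sult1e1 (21.7-fold), the opioid peptide gene Penk (13.9-fold) and Inmt (9.90-fold). Pdgfra itself was 2.62-fold lower (2.45 to 2.81) and Pdgfrb 1.45-fold lower (1.31 to 1.61). Further log2 ratios were Myoc at 4.73, Krtdap at 4.25, Fndc1 at 3.82, Sbsn at 3.81, Fndc5 at -4.19, Vtn at -3.96, Tcf21 at -3.58 and Alkal2 at -3.57.

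Across lists, Dpp4-type genes were higher in 16 of 16 in Pdgfrb-Cre over Pdgfra-Cre stroma (median 2.69, percentile 100), extracellular matrix genes in 21 of 27 (0.79, percentile 100, Col14a1 at 3.41 and Fn1 at 2.74) and inflammatory genes in 18 of 22 (1.53, percentile 100). Ptgs2, the inducible prostaglandin synthase, was 12.9-fold higher, Ccl2 7.91-fold higher and Cxcl2 9.13-fold higher (8.24 to 10.1). Senescence-associated genes stood at 0.43 (16 of 24 higher, interval -0.65 to 1.61, percentile 99.7) and MHC class II at 1.43 (4 of 4, percentile 99.99). The mitochondrial genome stood at 0.30 (9 of 13 higher, percentile 86.1) and heat shock at 0.22 (11 of 14 higher, percentile 84.7). Icam1-type genes were lower in 12 of 15 (-0.65, percentile 0.05, Ggt5 at -2.66 and Hsd11b1 at -2.48). F3-type genes were lower in 7 of 9 (-1.01, interval -1.93 to 0.51, percentile 0.05, F3 at -1.93) and adipogenesis genes in 13 of 19 (-0.31, percentile 4.71, Lpl at -1.37). Lower as well were interferon response genes in 18 of 24 (-0.30, percentile 3.31), immediate early genes in 18 of 25 (-0.40, percentile 0.1) and nuclear oxidative phosphorylation genes in 28 of 32 (-0.32, percentile 0.44).

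Near 0 between the Cre libraries were telomere maintenance (-0.14, 10 of 11 lower, percentile 52.98), oxidative stress (0.05, 11 of 20 higher, percentile 67.4), proliferation (-0.12, 3 of 4 lower, percentile 55.3), p53 targets (-0.02, 11 of 19 lower, percentile 84.4) and hypoxia and glycolysis (-0.01, 11 of 19 lower, percentile 71.8). Signs of the p53 and hypoxia medians turned under both other scalings and that of proliferation turned under one, and to 0.54 with the stricter filter and 0.44 with doublets kept. Without cluster 24, medians between the Cre libraries were 0.47 for Dpp4-type, 0.23 for Icam1-type, 0.16 for adipogenesis and 0.29 for immediate early genes, and -0.11 for the mitochondrial genome.

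Regulators that mark body position differed between the stromal cells of the libraries; these genes were chosen after their values were seen. Wt1 (chromosome 2, 105126529 to 105173616), a transcription factor of the visceral mesothelium and of visceral fat stroma, had 1, 837 and 4 UMIs, or 1.14, 147 and 0.660 CPM, a ratio of 129 (23.0 to 5088) for Pdgfra-Cre over wild type. Tcf21, another visceral stromal factor, had 3, 690 and 6 UMIs (ratio 35.4, 12.1 to 172). Factors known from subcutaneous stroma went the opposite way: Tbx15 (chromosome 3, 99240381 to 99354259) had 31, 0 and 256 UMIs, Shox2 59, 0 and 216, and Tbx5 10, 0 and 107. These were at least 67.2-fold, 128-fold and 21.7-fold lower in Pdgfra-Cre than in wild type. En1, Hoxc10 and Hoxa10 were 16.1-fold (8.96 to 30.1), 21.4-fold (11.5 to 42.1) and 28.5-fold lower (12.97 to 71.0). Not every Hox gene was lower in Pdgfra-Cre. Hoxc8 was alike in Pdgfra-Cre and wild type (ratio 1.135, 0.892 to 1.46), Hoxa5 (9.01-fold, 3.82 to 27.95) and Hoxa7 (3.47-fold, 2.22 to 5.73) were higher in Pdgfra-Cre, and Pdgfrb-Cre was itself lower than wild type in Hoxa10 (4.18-fold, 2.66 to 6.46), Hoxa9 (3.74-fold, 2.25 to 6.09) and Hoxc8 (2.66-fold, 2.01 to 3.48). In the 124 Pdgfra-Cre stromal cells outside cluster 24, Wt1 had 62 UMIs and Tbx15, Shox2 and Tbx5 had 0. Every stromal comparison with the Pdgfra-Cre library includes this difference.

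**Figure D3:**
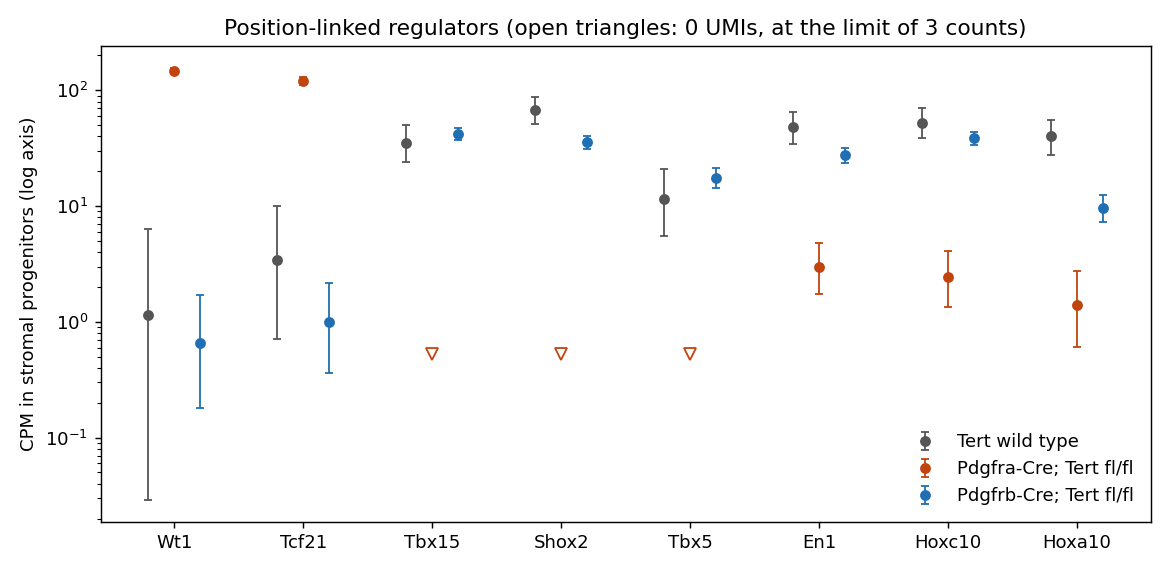
CPM (log axis) of regulators of body position in stromal cells of each library, with 95% Poisson intervals for counting error; open triangles mark 0 UMIs, drawn at the limit of 3 counts. Wt1 is at 147 CPM in Pdgfra-Cre against 1.14 in wild type and 0.660 in Pdgfrb-Cre, and Tbx15, Shox2 and Tbx5 have 0 UMIs there.

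The spread of log2 ratios over 3658 expressed genes, a measure of how far libraries lie apart, was 0.97 in stromal cells for Pdgfra-Cre and wild type, 0.79 for Pdgfrb-Cre and wild type and 0.90 between the Cre libraries. In blood endothelial cells it was 0.57, 0.62 and 0.52 (over 3730 genes), and in T cells 0.73, 0.75 and 0.61 (over 2567 genes). Single pairs gave 0.80 in macrophages (3221 genes), 0.76 in B cells (2618 genes) and 0.56 in NK cells (2885 genes). The median over all genes was itself above 0 in T cells of Pdgfra-Cre over wild type (0.14) and in B cells of Pdgfrb-Cre over wild type (0.12), and size factors shift ratios by about as much there.

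Blood endothelial cells (clusters 3, 5, 7 and 12, with 623, 123 and 199 cells) had immediate early and inflammatory medians above 0 in both Cre libraries over wild type. Immediate early genes were higher in 24 of 25 in Pdgfra-Cre (0.97, percentile 100) and 23 of 25 in Pdgfrb-Cre (0.87, percentile 100) over wild type, and inflammatory genes in 13 of 17 (0.68, percentile 100) and 14 of 18 (1.37, percentile 100). Of these inflammatory members 12 and 13 were higher in another class, and free RNA can add to their values. Csf3, the neutrophil growth factor, was at 0.439, 108 and 187 CPM, on 1 wild-type UMI, and Cdkn1a at 242, 1118 and 837 CPM. Apold1, Tmem252, Noct, Tnfrsf12a and Hbegf were also among the higher genes, as was Trim12a, whose reads can be shared with paralogs. Gdpd3 was lower in both Cre libraries (791, 1.08 and 2.32 CPM), as were Hspa1a (2654, 259 and 665) and Hspa1b (1172, 123 and 286), which share reads. Glycam1, a ligand of high endothelial venules, was at 558 CPM in wild type, 0 in Pdgfra-Cre and 30.6 in Pdgfrb-Cre, and H2-M9, whose reads can be shared with other class I genes, at 101, 0 and 36.6.

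The endothelial subtype list stayed near 0 (0.14, percentile 90.3, and 0.06, percentile 60.0, the former turning to -0.06 with calls per cell and the latter to -0.01 under one scaling and -0.17 over members of at least 50 CPM; -0.09, percentile 6.8, between the Cre libraries). Interferon response genes stood at 0.38, 0.07 and, between the Cre libraries, -0.34, heat shock genes at 0.10, 0.42 and 0.49, and the mitochondrial genome at -0.55, -0.64 and -0.09. Between the Cre libraries, inflammatory genes stood at 0.36, immediate early genes at 0.04 and the vessel-growth peptide Apln was at 71.3 CPM in Pdgfrb-Cre. Cluster 12 held 106 wild-type cells, 0 of Pdgfra-Cre and 2 of Pdgfrb-Cre.

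Macrophages (clusters 15 and 17) could be compared between Pdgfrb-Cre and wild type, with 185 and 128 cells. Inflammatory monocyte genes were higher in 14 of 17 (1.21, percentile 100) and inflammatory chemokines and cytokines in 11 of 17 (0.92, interval -0.32 to 1.61, percentile 100). Immediate early genes had a median of 0.66 (interval -0.06 to 0.96, percentile 99.98). Spp1, encoding osteopontin, was at 567 against 4.68 CPM on 3 wild-type UMIs (121-fold, 41.4 to 588), and Arg1, the arginine-degrading enzyme, at 87.6 CPM against 0 UMIs. H2-Eb1, an MHC class II chain, was at 93.5, 3426 and 4237 CPM. Its gap between wild type and Pdgfrb-Cre was not confined to macrophages, as B cells showed it too (given below). Interferon response genes were lower in 22 of 25 (-0.81, percentile 0), heat shock genes stood at -0.41 (percentile 0.22) and the mitochondrial genome at -0.50 (percentile 0.03). Hal, Lepr, Polr2l and Tspan10 were among the lowest genes, as was Ifi202b. Resident genes (0.07, percentile 40.1, turning to -0.0025 with size factors) and lipid-associated macrophage genes (-0.03, 10 of 19 lower, percentile 10.9) stayed near 0. Under 4 of the alternatives fewer than 100 macrophages were left in a library, so these values rest on the main clusters. At Leiden resolution 2, an unnamed cluster led by Plbd1, H2-DMb1 and Il1b, with H2-Eb1 also among its leading genes, held 78 wild-type and 68 Pdgfrb-Cre cells, and 51 and 118 macrophages were left. The values can therefore include a mix of macrophage-like and dendritic-like cells that differs between the libraries.

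T cells (clusters 6, 9, 19, 20 and 23) fell into different clusters by library: cluster 6 held 449, 16 and 19 cells, cluster 19 held 5, 16 and 767, and cluster 23 held 1, 83 and 481. The cytotoxic chemokine gene Ccl5 was at 362, 5913 and 2078 CPM and Ctla4, an inhibitory receptor, at 181, 34.5 and 177. Odc1, the first enzyme of polyamine synthesis, was at 1103 CPM in Pdgfrb-Cre against 65.5 in wild type, and the cytokine gene Il17a at 185 against 11.8 in Pdgfra-Cre and 20.7 in wild type. Dennd4a was at 387 CPM in Pdgfra-Cre against 33.7, and Slamf6 at 15.4 against 148. T cell state genes stood at 0.46 (12 of 20 higher, interval -0.30 to 0.95, percentile 99.5) in Pdgfra-Cre, 0.01 (percentile 37.4, with a sign that turned under both other scalings) in Pdgfrb-Cre and -0.17 (percentile 20.3) between them.

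Inflammatory genes in T cells stood at 0.24 (interval -0.70 to 0.79) and 1.05 (-0.98 to 1.60) over wild type on 6 measured members, 4 of them higher in another class, immediate early genes at 0.24 and 0.28 and interferon response genes at -0.31 and -0.34. In B cells (clusters 2 and 4), where wild type and Pdgfrb-Cre could be compared, H2-Eb1 was at 184 against 4664 CPM and the adhesion receptor gene Slamf1 at 309 against 6.43. Interferon response genes stood at -0.67 there, with 14 of 16 measured members higher in another class. Inflammatory genes stood at 0.84 on 7 measured members (interval of the median -0.78 to 1.23), 6 of them higher in another class, so free RNA of other cells can carry both values. NK cells (cluster 8), compared between the Cre libraries, had inflammatory genes at 0.85 (9 measured members, 6 of them higher in another class) and interferon response genes at -0.59. This class held 188 and 127 cells, of which the other Leiden resolutions left 73 and 74 in Pdgfra-Cre and 67 in Pdgfrb-Cre with more T cells, so its values can include T cells in unequal parts.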

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

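The tests of depth and of whole libraries for the cycling share and of RNA of mesothelial cells were chosen after their results were seen, and those of a strain difference, of chromosome 13, of free RNA of cycling lymphocytes, of a mixture of fat pads and of position-linked genes in vessel cells were written before.

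In the Pdgfra-Cre library, 34.6% of the barcodes under 500 genes (279 of 807, 31.3 to 38.0) consisted mostly of haemoglobin UMIs, a signal in barcodes that the comparisons do not use, against 0.167% in wild type and 1.45% in Pdgfrb-Cre. The median of the interstitial Dpp4-type progenitor genes against wild type was -2.54 in Pdgfra-Cre and 0.36 in Pdgfrb-Cre stromal cells, opposite directions in the Cre libraries, and that difference was not tested. Without cluster 24 the Pdgfra-Cre median was -0.17.

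Stromal cells of the Pdgfra-Cre library carried Wt1 and Tcf21 and had 0 UMIs of Tbx15, Shox2 and Tbx5, the reverse of both other libraries. RNA of mesothelial cells is argued against, since Wt1 UMIs per UMI of Upk3b, Krt19 and Lgals7 were 233-fold more frequent in stromal than in mesothelial cells (211 to 258). A mixture of inguinal stroma with stroma of another fat pad cannot be told apart, since En1, Hoxc10, Hoxa9 and Hoxa10 together were 1.93-fold higher in stromal cells without a UMI of Wt1 or Tcf21 than in those with one (0.990 to 3.60), an interval too wide to decide, but inguinal stroma would be a small part, as these cells stood at 0.0815 of wild type (0.0454 to 0.137). Whether the whole stroma came from another fat pad than the label states was not settled. In blood endothelial and mural cells, Tbx15, Shox2, Tbx5, En1, Hoxc10, Hoxa9 and Hoxa10 were summed. They were 4.37-fold higher in wild type (2.84 to 7.05) and 3.41-fold higher in Pdgfrb-Cre (2.20 to 5.53) than in Pdgfra-Cre. Both lower bounds were under the 3-fold set beforehand. Free stromal RNA is argued against as their main source. Per Col1a1 UMI they were 36.16-fold more frequent than in stroma in wild type (30.01 to 43.55) and 25.86-fold in Pdgfrb-Cre (21.83 to 30.48). An effect of the genotype confined to stromal cells leaves this gap unexplained. Mural cells, which the drivers can mark, were not counted apart, so a wider effect of the genotype stays open, untested. Mesothelial cells, which cover visceral fat, were also 9.23% of the Pdgfra-Cre library, against 2 cells in Pdgfrb-Cre and 0 in wild type. That share was not part of these tests. Tests of stromal levels between libraries were dropped, since their genes had been chosen for this pattern.

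In stromal cells, 72 genes differed at least 10-fold between wild type and both Cre libraries, 63 of them higher in wild type, and some also differed in other classes, such as Gdpd3 in 7 of 7. DNA around Tert carried along with the floxed allele is argued against as the cause of the set, since 2 of the 72 genes lay on chromosome 13 (2.78%, 0.338 to 9.68). A strain difference between the mice cannot be told apart from other causes: 31 of the 63 genes that could be measured elsewhere (49.2%, 36.4 to 62.1) had a gap of at least 4-fold the same way in another class, an interval too wide to decide. The set also holds cell-cycle and lymphocyte genes, which keeps it open. An effect of losing Tert stays open as well, untested.

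Cycling stromal cells were common in wild type and rare in both Cre libraries. Depth per cell is argued against, since with equal UMIs per cell the lower bound in wild type was 15.1% and the upper bounds were 0.640% and 1.002%. Free RNA of cycling lymphocytes is argued against as the whole source, since Cd79a, Cd79b, Cd3e, Ptprc and Cd52 per UMI of the cell-cycle genes stood in wild-type stromal cells at 0.441 of their level in cluster 0 (0.388 to 0.499). A difference of whole libraries, beyond the cells the drivers mark, may be a source. Cells neither stromal nor mural were cycling at 5.30% in wild type (4.31 to 6.44), with upper bounds of 3.09% and 3.39% in the Cre libraries. Endothelial cells were cycling at 6.35% (4.07 to 9.38), with 3.89% and 3.93%. Without thinning, however, the intervals of wild type and Pdgfrb-Cre overlapped in both sets of cells, and those of wild type and Pdgfra-Cre in endothelial cells. The first set includes cluster 0, led by cell-cycle genes (139, 8 and 58 cells), which can carry its share. After thinning, T cells were cycling at 0.374% in wild type and 0.961% in Pdgfrb-Cre, and B cells at 0.347% and 1.07%, with overlapping intervals. Pdgfra-Cre had 0 cycling T cells (up to 2.48%) and B cells (up to 14.8%). Lower division after loss of Tert in stromal cells stays open, untested.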

How the results depend on the processing

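No paired analysis was possible because each genotype was 1 library, and a replicate number of 1 in every group links no samples. Of 757 list medians recomputed under the alternatives, 728 stayed within the order-statistic interval over their members, 24 moved beyond it and 5 reversed. In all, 47 list medians changed sign, the other sign changes being of medians that did not stand apart from 0, by an interval over members without 0 or a percentile outside the central 95%. Of 1275 values of named genes 121 moved beyond their interval and 0 reversed, as 1 gene that lay within counting error (Pdgfrb, Pdgfrb-Cre over wild type) changed sign. Of 216 shares 108 moved, such as the NK share of Pdgfra-Cre, from 13.3% to 2.98 to 5.25%, and its T cell share, from 11.1% to 19.3 to 24.1%. Of 95 library distances 24 moved and of 13 cycling shares 4. Where no cause is named, the cause was not tested.

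Without cluster 24, chosen after the data were seen and leaving 124 Pdgfra-Cre stromal cells, medians over wild type were -0.0001 for adipogenesis and -0.32 for inflammatory genes, both reversed, -0.17 for Dpp4-type genes and 1.16 for immediate early genes. Between the Cre libraries they were 0.23 for Icam1-type and 0.285 for immediate early genes, both reversed, and 0.47 for Dpp4-type genes. Without cluster 18, also chosen later, which held most of the wild-type cycling stromal cells, the wild-type cycling share was 3.45%. The proliferation median was then -0.0495 in Pdgfra-Cre and -0.68 in Pdgfrb-Cre. A mean over cells reversed the F3-type median of Pdgfrb-Cre over wild type to 0.53 and gave stromal library distances of 1.03 and 0.85 to wild type.

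A pseudocount of 1 raised those distances to 1.25 and 0.97, and to 1.13 between the Cre libraries, and gave proliferation medians of -3.66 and -3.48, since a lower pseudocount widens ratios of weak genes. With members of at least 50 CPM, which leaves fewer genes, these were -2.69 and -2.51, and the p53 medians were 0.97 and 1.13. With doublets kept, proliferation stood at -1.23 for Pdgfrb-Cre over wild type and 0.44 between the Cre libraries, and with the strict filter at 0.54 between them. Under that filter stromal shares were 48.0% in Pdgfra-Cre and 28.2% in Pdgfrb-Cre, and the wild-type cycling share 29.2%. Leiden resolution 2 gave a Pdgfra-Cre stromal share of 38.2%. Among cells that are not lymphoid, stromal shares were 18.02%, 59.6% and 51.2% and the mesothelial share of Pdgfra-Cre 12.5%, by the smaller denominator. Without thinning, cycling shares were 0.969% and 1.41% in the Cre libraries.

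The strict filter left 72 wild-type stromal cells and 61 Pdgfra-Cre endothelial cells, so it gave no ratio there. Macrophages fell under 100 cells with the strict filter, with doublets kept, at resolution 2 and with calls per cell, and NK cells in these and at resolution 0.5. Depth limits Tert and other weak genes, which had at most 4 stromal UMIs for Tert in a library.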

Other observations

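The test of cells with Xist was chosen after its result was seen.

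Beyond the stroma, cycling macrophages were 10.1% in wild type (4.73 to 18.3), 0% in Pdgfra-Cre (up to 4.86%) and 4.598% in Pdgfrb-Cre (2.01 to 8.86) after thinning, and 14.06%, 8.08% and 16.8% without it, which turns the direction between wild type and Pdgfrb-Cre. Cluster 20, led by the interleukin-17 gene Il17a and the gamma-delta receptor gene Trdc, held 16, 36 and 215 cells. Cluster 9, led by Ikzf2 and Ctla4 with Foxp3 among its leading genes, markers of regulatory T cells, held 115, 6 and 197 cells. B cells split by library as well, with 606, 2 and 21 cells in cluster 2 and 8, 23 and 932 in cluster 4. Lymphatic endothelial cells made up 0%, 1.07% and 0.128% of cells, plasma cells 0.412%, 0.0710% and 0.820%, and neutrophils 0.900%, 0.497% and 0.461%. Schwann cells made up 0.375%, 0.142% and 0.0769%, and mast cells or basophils 0%, 0.142% and 0.205%.

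Heat shock genes stood at -0.59 (percentile 0) in T cells of Pdgfra-Cre over wild type, -0.14 for Pdgfrb-Cre and 0.16 between the Cre libraries, and the mitochondrial genome at -0.38, 0.09 and 0.62. In B cells of Pdgfrb-Cre over wild type, immediate early genes stood at 0.35, heat shock genes at -0.41 and the mitochondrial genome at -0.18. In NK cells between the Cre libraries, immediate early genes stood at -0.41, heat shock genes at 0.21 and the mitochondrial genome at 0.66, values that can include T cells grouped with them. Interferon response genes stood at 0.15 and inflammatory genes at 0.70 in T cells between the Cre libraries.

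The Pdgfra-Cre library held 206 UMIs of Xist, the transcript of an inactive X chromosome, against 2 in wild type and 1 in Pdgfrb-Cre. Of its cells, 15 had at least 3 Xist UMIs, 12 of them among its 25 B cells, and 0 of these 15 had a UMI of a Y-linked gene, while 66.5% of the library's cells had one (45.5% in wild type and 72.5% in Pdgfrb-Cre). Cells of a second, female animal in this library may be the source: the 15 cells had 0 Y-linked UMIs where the rate of the other 19 cells of their classes would give 33.55, a ratio of at most 0.119. The B cell share of this library can then include cells of that animal, and other sources were not tested.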
